A study of Nitrobacter winogradskyi with 9 samples.

How the data were processed

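Total RNA of Nitrobacter winogradskyi from chemostats with 0, 1 or 25 mM ammonium, 3 biological replicates each per the labels, had rRNA removed with MICROBExpress and was sequenced on an Illumina instrument. The submitters' processing notes name Bowtie2 2.1.0. The counting tool, the genome build, the strandedness of the library and the authors' test are not given in the sources used here. Per the file headers the values per gene and library are pseudo counts of unique reads. From the values, the authors drew deposited counts at random from the reads of libraries, so that the 6 libraries of a table have about the same total. The draws differed between the 3 comparisons, except that 0 mM replicate 1 held the same counts in both tables with 0 mM. Totals per library were 8263112 to 8264994 counts for 1 against 0 mM, 8262336 to 8265825 for 25 against 0 mM, and 11284201 to 11287580 for 25 against 1 mM. As a check, 1 mM replicate 2 kept 73.2% of its reads between the larger and the smaller table. The variance over 2851 genes was 0.996 of that of a binomial draw, and 0 genes had more reads after it. The authors' deposited log2 fold changes equal the log2 ratio of the summed counts of the groups. The authors' deposited p-values come unadjusted, from a test that the file headers do not name.

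The authors' own table held, at 25 against 1 mM, 492 genes higher and 114 lower at a p-value under 0.05, and 128 and 47 after Benjamini-Hochberg adjustment. For 25 against 0 mM it held 737 and 209, and 243 and 145 after adjustment, and for 1 against 0 mM 46 and 113, and 0 and 2. These values were used for no other count. The workbook of the series holds a second version of the counts of both comparisons with 25 mM, used as an alternative. In it 0 mM replicate 1 (25 against 0 mM) and 1 mM replicate 2 (25 against 1 mM) had identical counts in 100% of genes, and the other libraries another random draw. It also gave product names, for 2252 of 3198 genes. Its 6 columns of values for 1 against 0 mM were not used, because 3 of them carry the name of 0 mM replicate 1. Each table held 3197 genes, and Nwi_0761 was left out because its counts there exceeded those in the workbook by far and 1 gene, Nwi_0223, stood in the workbook alone.

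Genes were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM scaling, filterByExpr by group) at a Benjamini-Hochberg adjusted p under 0.05. The plan, written before the data were examined, was 1 fit of all 9 libraries. Because the authors thinned each table separately, each comparison was instead fitted within its own 6 libraries, before any gene was tested, and the fit of all 9 became an alternative. SE is the log2 fold change divided by the square root of F. CPM uses the TMM-scaled totals. The stable RNA genes (55 of them, tRNA, rRNA, transfer-messenger RNA and the like) stayed in the totals and were left out of gene lists and their background. Shares of stable RNA were compared by exact two-sided permutation tests in Python 3.11.15 with scipy 1.17.1 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9). Their SD describes replicates, and counting error is far smaller at these totals. The number of counts limits precision for genes of low CPM.

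Gene lists were fixed before the data were examined, by patterns on product names or symbols: 23 lists of coding genes and 1 of structural RNA. Of these, 22 had at least 4 measured members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset correlation of 0.01, and again with an estimated correlation and with fry. Fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes. Lists edited after reading the annotation, and a Flp pilus list chosen after the values were seen, were alternatives. Named genes followed a rule fixed beforehand. It took the 6 largest changes in each direction among genes past the threshold with all 3 libraries of one group above the 3 of the other and a mean of at least 10 CPM, and the 6 largest with a known product. It also took up to 2 members of each list with the smallest p, and 19 genes of ammonium assimilation, nitrite oxidation, carbon fixation and quorum sensing whatever their values. An ammonium transporter was part of the rule and was not found in the annotation.

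In simulated data with 200 changed genes, the same test recovered 51.5% of 97 genes changed 2-fold and 99.0% of 101 changed 4-fold at 25 against 1 mM. Of changes at 25 against 0 mM it recovered 4.20% of 119 and 67.1% of 79, and at 1 against 0 mM 1.05% of 95 and 67.0% of 100, with 7, 2 and 1 false calls. The common coefficient of variation was 0.254, 0.419 and 0.408 in that order. Whether replicate numbers mark pairs is not stated by the labels. Residuals of equal number correlated at 25 against 1 mM at 0.188, 0.155 and 0.185, all positive, so the replicate number was also fitted as a block. At 1 against 0 mM they correlated at 0.232, -0.274 and 0.231, and at 25 against 0 mM at 0.299, -0.258 and 0.395.

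Alternatives planned beforehand were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter of at least 10 CPM in 3 libraries, a fold threshold of 2, stable RNA left out, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were the block within 6 libraries, the fit of all 9 libraries without 0 mM replicate 3, the second version of the counts and the edited lists. Overlap between comparisons that share a group was set beside 100 simulations of unchanged groups (10 for shared calls, seed 1). Reads that fit several near-identical genes, such as copies of nitrite oxidoreductase or transposases, are not among unique reads, so levels of such copies are those of their unique parts. Levels drawn for all 9 libraries come from tables thinned separately. Genome coordinates were not used here.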

Results

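Nitrobacter winogradskyi, a bacterium that lives by oxidising nitrite to nitrate, was grown in chemostats fed 60 mM nitrite at a dilution rate of 0.008 per h with 0, 1 or 25 mM ammonium, and RNA of 3 libraries per ammonium level was sequenced. The replicates are biological per the labels. Levels are normalised read counts (CPM, as edgeR scales them) with the SD over the 3 replicates. Differences are log2 fold changes ± SE with Benjamini-Hochberg adjusted p from edgeR, each comparison resting on 6 libraries. Totals per library lay between 8262336 and 8265825 counts in both tables with 0 mM, and between 11284201 and 11287580 in the table of 25 against 1 mM. Transfer, ribosomal and other stable RNA took 78.6 ± 2.15% of the counts at 0 mM, 81.0 ± 7.99% at 1 mM and 74.9 ± 6.17% at 25 mM (SD, n = 3 each). Transfer-messenger RNA, which frees stalled ribosomes, took 28.4 ± 7.50% at 25 mM, 14.3 ± 3.76% at 1 mM and 16.6 ± 5.10% at 0 mM (SD, n = 3 each). Exact two-sided permutation tests of the shares of stable RNA, 23S rRNA and transfer-messenger RNA made 9 relations. Their smallest p, 0.1 for transfer-messenger RNA at 25 against 1 mM, is the smallest that 3 against 3 libraries allow, and its Benjamini-Hochberg value was 0.54.

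Across coding genes, 0 mM replicate 3 stood apart from its group. Its log2 CPM values correlated across genes with those of 0 mM replicates 1 and 2 at r between 0.769 and 0.771, against 0.978 between those replicates. With the 1 mM libraries it correlated at 0.898 to 0.921 and with the 25 mM libraries at 0.905 to 0.940. At 25 mM, replicate 1 correlated with replicates 2 and 3 at 0.928 and 0.944, against 0.986 between those. Genes are not independent replicates, so no p is given for these correlations. Copper nitrite reductase (nirK, Nwi_2648), which reduces nitrite to nitric oxide, stood at 551 CPM in this library, at 6.47 and 6.74 CPM in the other libraries at 0 mM and at 10.01, 77.1 and 73.4 CPM in 25 mM replicates 1, 2 and 3. Counts of genes in the comparisons with 0 mM were also taken without this library.

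**Figure D1:**
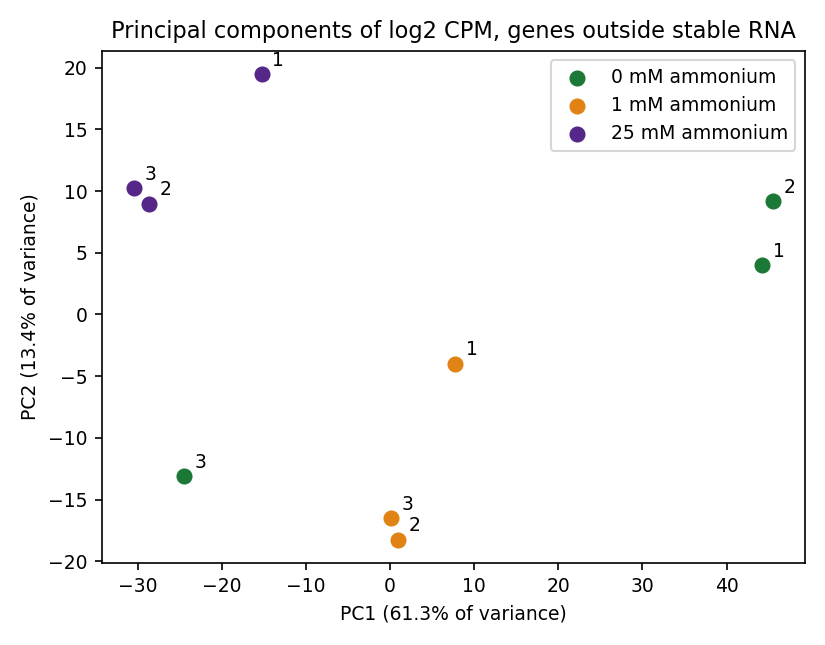
Principal components of log2 CPM of coding genes in the 9 libraries; the x axis is component 1 (61.3% of the variance), the y axis component 2 (13.4%), and each point is 1 library. At 0 mM, replicates 1 and 2 lie at 44.2 and 45.5 on component 1 and replicate 3 at -24.5.

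At 25 against 1 mM ammonium, the lists of ATP synthase, protein folding, ribosomal protein and translation genes shifted upward and those of motility and signalling genes downward, and single genes of metal efflux, glycogen turnover and stress proteins were lower at 25 mM. These list shifts are calls of camera with a preset correlation, and all 6 were lost at adjusted p = 0.326 to adjusted p = 0.367 with an estimated correlation. ATP synthase, which makes ATP from the proton gradient, had 8 of 11 measured genes higher and 0 lower, with a median log2 fold change of 1.13. Its gamma subunit (Nwi_0431) rose from 23.9 ± 8.69 to 81.2 ± 10.8 CPM (SD, n = 3 each), a log2 fold change of 1.77 ± 0.27. In the flagella and chemotaxis list, 23 of 54 measured genes were lower and 3 higher, with a median of -0.72. The largest fall among the named genes was that of Nwi_0960, which has no product name, from 260 ± 74.9 to 16.7 ± 7.06 CPM (-3.97 ± 0.37, SD, n = 3 each). By edgeR, 215 genes were higher and 307 lower at 25 mM of 2970 tested, at an adjusted p under 0.05.

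The largest rise among the named genes was that of Nwi_0922, annotated as a GreA/GreB transcription elongation factor, which act on stalled RNA polymerase, at 3.07 ± 0.42 (adjusted p = 0.00351). Genes without a product name, Nwi_3102, Nwi_3101, Nwi_3103 and Nwi_2721, rose by 2.54 ± 0.37, 2.05 ± 0.30, 2.01 ± 0.49 and 2.21 ± 0.43. An esterase gene (Nwi_0416) rose by 2.14 ± 0.34, thioredoxin (Nwi_0051), a thiol-disulfide reductant, by 1.94 ± 0.34, and a FecI-like sigma factor (Nwi_2303) by 1.90 ± 0.44. Genes of CsbD-like proteins, known from bacterial stress responses, were lower, Nwi_2245 at -3.53 ± 0.48 and Nwi_2997 at -2.95 ± 0.45. A universal stress protein (UspA, Nwi_1035) was lower at -2.79 ± 0.28, a gene of a family 15-related glycoside hydrolase (Nwi_2309) at -2.93 ± 0.52, and the type I secretion ATPase PrtD (Nwi_0962), part of a protein exporter, at -3.56 ± 0.52. Nwi_2766, without a product name, and Nwi_1635, annotated as hypothetical, were lower at -3.48 ± 0.31 and -3.44 ± 0.55.

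In the ATP synthase list 9 genes were higher and 0 lower when adjusted over the list alone, and the alpha subunit (Nwi_0430) rose from 76.6 ± 9.06 to 176 ± 11.1 CPM (SD, n = 3 each). Protein folding and heat shock genes, whose products refold or degrade proteins, had 11 of 37 measured members higher and 0 lower (12 and 0 adjusted over the list alone), with a median of 0.86. The co-chaperone GrpE (Nwi_0195) rose by 1.94 ± 0.32 and a small heat shock protein (Hsp20, Nwi_2940) by 1.35 ± 0.22. Ribosomal protein genes had 5 of 55 higher and 0 lower, the same counts when adjusted over the list alone, with a median of 0.59, and among them rplL (Nwi_1349) rose by 1.15 ± 0.17 and rpsB (Nwi_1859) by 1.12 ± 0.18. Translation factors and aminoacyl-tRNA synthetases, which charge tRNA and drive peptide synthesis, had 4 of 35 higher and 1 lower (4 and 1 adjusted over the list alone), with elongation factor Ts (tsf, Nwi_1858) at 1.36 ± 0.21. This list also holds Nwi_0922, annotated for transcription and not for translation. By camera with a preset correlation, these lists shifted upward at adjusted p = 4.3e-05 for ATP synthase, 1e-05 for protein folding, 1e-05 for ribosomal proteins and 0.00797 for translation. Each of the 4 calls was lost with the other setting of camera, at adjusted p = 0.326 with an estimated correlation.

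Flagella and chemotaxis genes, which build and steer the swimming apparatus, had 4 members higher and 28 lower when adjusted over the list alone. A chemotaxis methylesterase (Nwi_0523), which resets receptors, was lower at -2.30 ± 0.23 and a gene related to flagellar export (Nwi_1400) at -2.42 ± 0.24. The 3 higher members, Nwi_0703, Nwi_2305 and Nwi_1814, the last 2 chosen after their values were seen, are annotated as ExbB, ExbB and OmpA/MotB, proteins that power outer membrane transport or anchor the envelope. Camera gave a downward shift at adjusted p = 1e-05, and adjusted p = 0.367 with an estimated correlation. Quorum sensing and signalling genes, among them diguanylate cyclases and phosphodiesterases that set cyclic di-GMP, had 4 of 14 lower and 0 higher, also adjusted over the list alone, among them Nwi_2896 (-0.94 ± 0.18) and Nwi_2716 (-0.84 ± 0.17). Their camera call, adjusted p = 0.0391, became adjusted p = 0.326 with an estimated correlation of 0.0186, near the preset 0.01. It was also lost without 25 mM replicate 1 (0.0923), 25 mM replicate 2 (0.0632), 1 mM replicate 2 (0.0529) or 1 mM replicate 3 (0.0737). With the replicate number as a block it was 0.0657.

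No other list fixed beforehand passed camera at 25 against 1 mM with all 6 libraries. Iron uptake and storage passed it with edited lists (adjusted p = 0.0400, and adjusted p = 0.292 with an estimated correlation) and without 1 mM replicate 1 (0.0262), and NADH dehydrogenase without 1 mM replicate 2 (0.0289). Iron uptake and storage had 7 of 51 members higher and 1 lower (7 and 1 adjusted over the list alone), with a TonB-dependent receptor (Nwi_2902) at 0.78 ± 0.17 and ExbB (Nwi_0703) at 1.09 ± 0.24. Metal efflux had 3 of 16 lower and 0 higher, also adjusted over the list alone, with the CzcB-like membrane fusion protein (Nwi_2912) lower at -3.68 ± 0.46 and a metal-translocating ATPase (Nwi_1949) at -1.40 ± 0.19. Its median of 0.01 and mean of -0.31 differed in sign, as did those of denitrification (-0.02 and 0.13), and camera gave an upward direction for ammonium assimilation and carbon dioxide fixation, whose medians were -0.17 and -0.03. Storage polymers had 2 of 10 lower and 0 higher (2 and 1 adjusted over the list alone), both of glycogen metabolism: the branching enzyme (Nwi_1207, -2.30 ± 0.34) and the debranching enzyme GlgX (Nwi_1206, -1.80 ± 0.29). Oxidative stress defence had 4 of 19 higher and 1 lower (5 and 1 adjusted over the list alone), the lower one a peroxidase-like gene (Nwi_0492, -1.89 ± 0.19). In the nitrite oxidation list 2 of 5 members were lower and 0 higher, also adjusted over the list alone, but these are annotated as NorC (Nwi_2313, -2.20 ± 0.37) and NorB (Nwi_2314, -1.19 ± 0.25), names of a nitric oxide reductase, and not as nitrite oxidoreductase. Terminal oxidases and cytochromes, a list that also holds both, had 3 of 31 higher and 3 lower, also adjusted over the list alone.

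Amino acid biosynthesis had 3 of 55 members higher and 2 lower, also adjusted over the list alone, with hisB of histidine synthesis (Nwi_0126) at 1.33 ± 0.23 and murE (Nwi_1046), which acts in cell wall synthesis, at -0.84 ± 0.17. Of the genes that use nitrite, nitrate or other nitrogen sources, 2 of 14 were lower and 0 higher, also adjusted over the list alone, a formate/nitrite transporter (Nwi_3006, -1.54 ± 0.35) and a nitrate/sulfonate transporter gene (Nwi_2680, -0.98 ± 0.17). NADH dehydrogenase, the entry of electrons from NADH, had 2 of 17 higher and 0 lower (0 and 0 adjusted over the list alone), Nwi_1874 at 0.67 ± 0.18 and Nwi_1875 at 0.72 ± 0.20. Mobile elements had 3 of 103 higher and 7 lower (0 and 6 adjusted over the list alone), with integrase genes Nwi_2105 at -1.54 ± 0.27 and Nwi_1140 at -0.90 ± 0.18. Outer membrane and multidrug transport had 2 of 37 higher and 3 lower, also adjusted over the list alone, with a polysaccharide export gene (Nwi_1414) at -2.04 ± 0.31 and the pump gene czcA (Nwi_2911) at -1.59 ± 0.22. Osmotic stress and ion transport had 1 of 11 higher, a glycine betaine transporter (Nwi_2340, 1.34 ± 0.26), and 1 lower, a trehalose synthesis gene (Nwi_1205, -1.58 ± 0.27), also adjusted over the list alone.

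Other list members past the threshold at 25 against 1 mM, chosen after their values were seen because their list had 5 or fewer in that direction, were as follows. Higher were the ribosomal protein genes rplQ (Nwi_1389, 1.16 ± 0.25), rplM (Nwi_1421, 1.19 ± 0.26) and rpsI (Nwi_1422, 0.90 ± 0.19), ribosome recycling factor (frr, Nwi_1856, 1.18 ± 0.20) and seryl-tRNA synthetase (Nwi_1776, 0.63 ± 0.16). Cytochrome c maturation genes were higher, ccmE (Nwi_1192) at 0.89 ± 0.22, ccmF (Nwi_1193) at 0.65 ± 0.19 and ccmH (Nwi_1194) at 0.87 ± 0.19, and a cytochrome c gene (Nwi_0694) was lower at -1.02 ± 0.23. Redox genes were higher, OsmC (Nwi_0432) at 1.21 ± 0.22, a glutaredoxin (Nwi_1312) at 0.89 ± 0.19 and thioredoxin reductase (Nwi_1089) at 0.93 ± 0.26. So were hisI of histidine synthesis (Nwi_1330, 0.96 ± 0.21), carB of carbamoyl phosphate synthesis (Nwi_2449, 1.01 ± 0.23), the small multidrug resistance gene sugE (Nwi_2028, 1.73 ± 0.38) and an outer membrane protein (Nwi_1337, 0.75 ± 0.21). Integrase genes Nwi_1293 and Nwi_0782 and a transposase (Nwi_0976) were higher at 0.92 ± 0.24, 1.32 ± 0.38 and 1.86 ± 0.51. Lower were elongation factor G (fusA, Nwi_2978, -1.06 ± 0.24), the cell wall gene Nwi_1047 (-0.67 ± 0.17), a TonB-dependent receptor (Nwi_0879, -0.98 ± 0.27), the efflux lipoprotein NodT (Nwi_2910, -1.42 ± 0.27), Nwi_2647 (-0.71 ± 0.20) and a LuxR family regulator (Nwi_0957, -0.81 ± 0.22). ExbB (Nwi_2305) and OmpA/MotB (Nwi_1814) rose by 1.82 ± 0.34 and 0.87 ± 0.18. Of these genes, frr, Nwi_0432 and Nwi_2305 kept their call without any 1 library, and every other was lost without 25 mM replicate 3, or for rplQ without 1 mM replicate 3, at adjusted p up to 0.168. Leaving out any 1 of the 6 libraries ended at least 1 of these calls.

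None of the ammonium assimilation, nitrite oxidoreductase or RuBisCO genes named beforehand passed the threshold at 25 against 1 mM by edgeR on all 6 libraries. Ammonium uptake and assimilation (9 measured), carbon dioxide fixation (25), conjugation (9), denitrification (6) and nitrogen regulation (3) had 0 members past it by edgeR, also adjusted over the list alone. With edited lists, denitrification had 2 of 7 lower and 0 higher, also adjusted over the list alone, and nitrite oxidation 0 of 8 past the threshold. Glutamate synthase, which with glutamine synthetase builds glutamate from ammonium, had values of 0.42 ± 0.20 (Nwi_2953, adjusted p = 0.189) and 0.49 ± 0.18 (Nwi_2954, adjusted p = 0.0979). Values were -0.30 ± 0.24 for glutamine synthetase (Nwi_1904), -0.32 ± 0.19 for glutamate dehydrogenase (Nwi_2286), and 0.28 ± 0.23, 0.18 ± 0.23 and -0.74 ± 0.62 for the PII nitrogen regulators Nwi_0076, Nwi_1903 and Nwi_2931. Nitrite oxidoreductase, the enzyme of nitrite oxidation, had values of -0.38 ± 0.44 and 1.14 ± 0.56 for its alpha subunit copies (Nwi_0774, Nwi_2068) and -0.27 ± 0.46 and -0.82 ± 0.56 for its beta subunit copies (Nwi_0776, Nwi_0965). RuBisCO, the carbon dioxide fixing enzyme, had 0.27 ± 0.44 and 0.40 ± 0.19 for cbbL (Nwi_1987, Nwi_2928) and -0.18 ± 0.23, 0.23 ± 0.62 and 0.12 ± 0.23 for cbbS (Nwi_1971, Nwi_1986, Nwi_2929). For nirK (Nwi_2648) the value was 1.40 ± 0.77, for the autoinducer synthase (Nwi_0626) -0.74 ± 0.32 and for its LuxR partner (Nwi_0627) 0.09 ± 0.18. Without 25 mM replicate 1, Nwi_2068 (1.55), Nwi_0965 (-1.76) and Nwi_0626 (-0.98) passed the threshold, and without 1 mM replicate 1 so did Nwi_0626 (-1.0025). With the replicate number as a block in the 6 libraries, nirK (1.19) and Nwi_2068 (0.99) passed it. No gene was annotated as an ammonium transporter.

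The counts at 25 against 1 mM moved with single libraries: without 25 mM replicate 1 they were 383 higher and 449 lower, without replicate 2 114 and 199, and without replicate 3 54 and 135. Without 1 mM replicates 1, 2 and 3 they were 141 and 282, 79 and 194, and 57 and 174. A fit of all 9 libraries called 35 higher and 117 lower, the same fit with the replicate number as a block 2 and 3. The fit of all 9 libraries without 0 mM replicate 3, added after the data were seen, called 245 and 364. Of these, 500 were also called in the fit of 6 libraries. Of 48 genes past the threshold that were named by rule, 15 lost their call without at least 1 library, at adjusted p up to 0.153. Nwi_1874, Nwi_1875, Nwi_2303 and Nwi_3103 lost it without any 1 of the libraries other than 25 mM replicate 1, and Nwi_0703, Nwi_2902 and Nwi_3006 without 25 mM replicate 2 or 3 or 1 mM replicate 2 or 3. Nwi_2716 lost it without 25 mM replicate 2 or 3 or 1 mM replicate 3, Nwi_1046 without 25 mM replicate 3 or 1 mM replicate 3, and Nwi_1140 and Nwi_2314 without 25 mM replicate 3 or 1 mM replicate 2. Nwi_2309, Nwi_2680 and Nwi_2896 lost it without 25 mM replicate 3 and Nwi_2721 without 1 mM replicate 3.

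**Figure D2:**
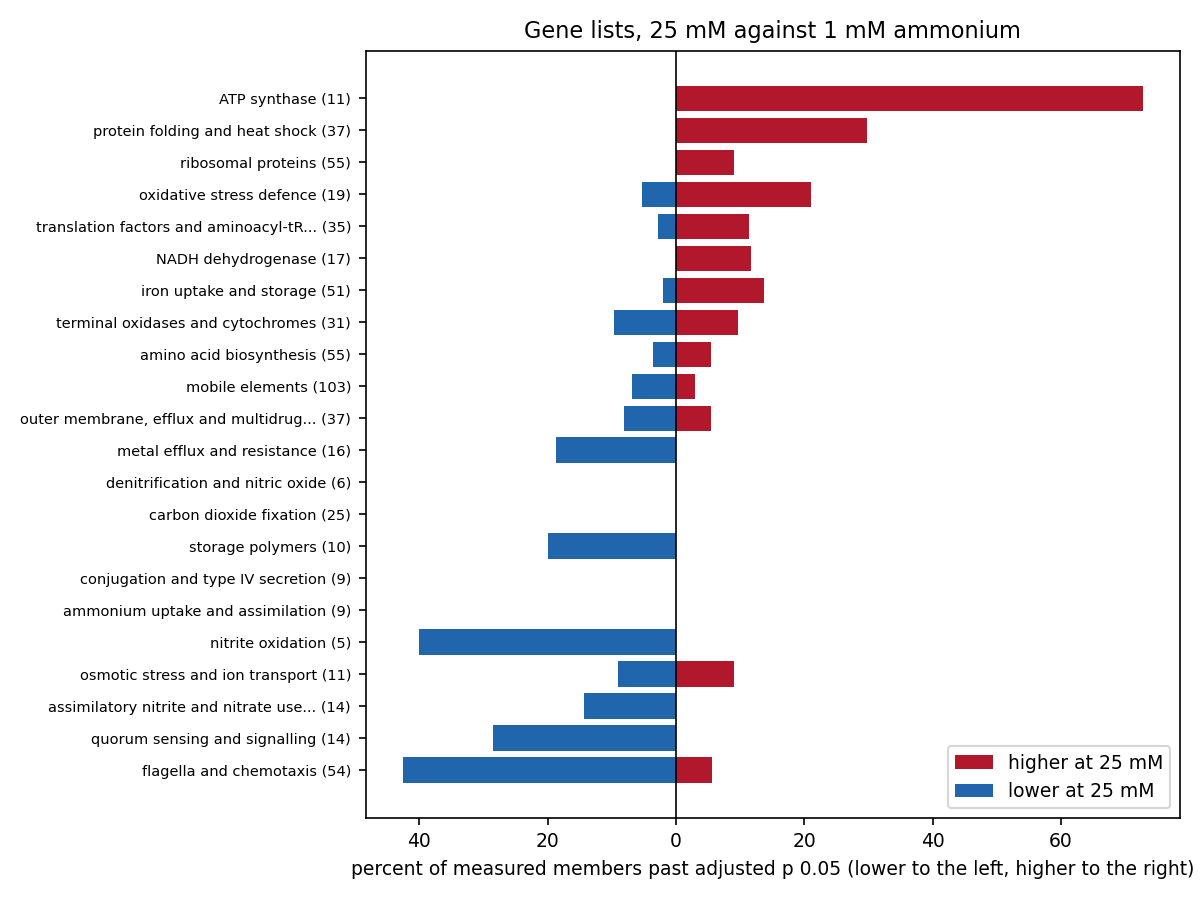
Percent of the measured genes of each list that were higher (right of 0) or lower (left of 0) at 25 than at 1 mM ammonium by edgeR at an adjusted p under 0.05; the x axis is percent, the y axis the list, and each bar is 1 list and direction. ATP synthase reaches 72.7% higher, and flagella and chemotaxis 42.6% lower.

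At 25 against 0 mM ammonium, the genes of cyanase, a pilus protein and a protein export ATPase and 7 motility genes were among those lower at 25 mM. Cyanase (cynS, Nwi_1302), which turns cyanate into ammonium and carbon dioxide, fell from 235 ± 145 to 17.1 ± 5.17 CPM (SD, n = 3 each), a log2 fold change of -3.78 ± 0.53 (adjusted p = 0.0228). In the flagella and chemotaxis list 7 of 54 measured genes were lower and 0 higher, led by the flagellar regulator flaF (Nwi_1106, -3.68 ± 0.48) and the chemotaxis kinase CheA (Nwi_0520, -2.85 ± 0.43). Nwi_0960 fell from 743 ± 217 to 16.4 ± 8.46 CPM (-5.51 ± 0.55, SD, n = 3 each) and the export ATPase PrtD (Nwi_0962) was lower at -4.06 ± 0.47. By edgeR, 2 genes were higher and 68 lower of 2934 tested, at an adjusted p under 0.05.

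The 2 higher genes were an ApbE-like lipoprotein (Nwi_2816), of a family that attaches flavin to proteins, at 1.67 ± 0.30 (adjusted p = 0.0430), and Nwi_3042, without a product name, at 1.44 ± 0.23 (adjusted p = 0.0326). Among the lower genes were the secretin-like pilus protein CpaC (Nwi_0301, -2.72 ± 0.42), a MarR family regulator (Nwi_1907, -2.68 ± 0.37) and the genes without product names Nwi_2971 (-3.31 ± 0.33) and Nwi_1995 (-2.85 ± 0.39). Nitrite reductase nirB (Nwi_0719), which turns nitrite into ammonium for assimilation, stood at 10.6 ± 3.65 CPM at 25 mM and 46.6 ± 23.5 CPM at 0 mM (-2.14 ± 0.47, adjusted p = 0.0726), lower in all 3 libraries but not past the threshold.

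Adjusted over the list alone, flagella and chemotaxis had 27 members lower and 1 higher, and its median was -0.92. The genes for nitrite, nitrate and other nitrogen sources had cynS as the only member past the threshold of 14 (4 lower and 1 higher adjusted over the list alone), with a median of -0.43. Quorum sensing and signalling had 1 of 14 lower, a cyclase and phosphodiesterase of cyclic di-GMP (Nwi_2647, -1.28 ± 0.23), and 4 lower adjusted over the list alone. Camera gave downward shifts at adjusted p = 3.7e-07 for flagella, 0.0143 for quorum sensing and 0.0382 for nitrogen sources. These became adjusted p = 0.649, 0.662 and 0.649 with an estimated correlation. Upward shifts by camera were those of protein folding (36 measured, median 0.55, adjusted p = 0.00477), ribosomal proteins (55, 0.07, 0.00477), amino acid biosynthesis (55, 0.20, 0.00770), ATP synthase (11, 0.81, 0.0143) and NADH dehydrogenase (17, 0.38, 0.0382, and 0.0574 with edited lists, no longer a call). For these 5 lists the values ran from adjusted p = 0.662 to adjusted p = 0.770 with an estimated correlation, and 0 members were past the threshold, also adjusted over the list alone. Examples not past it were the protease subunit hslU (Nwi_0129, 1.73 ± 0.47), GrpE (Nwi_0195, 1.31 ± 0.37), hisB (Nwi_0126, 0.92 ± 0.29) and the ATP synthase epsilon subunit (Nwi_0434, 0.97 ± 0.73).

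Camera calls at 25 against 0 mM were lost without single libraries for nitrogen sources (25 mM replicate 1, 0.0580, 25 mM replicate 2, 0.0587, and 0 mM replicate 3, 0.161), ATP synthase (25 mM replicate 1, 0.0549, and 0 mM replicates 1 and 2, 0.0609 and 0.0627), NADH dehydrogenase (25 mM replicates 1 and 2, 0.0679 and 0.0509, and 0 mM replicates 1 and 2, 0.216 and 0.251) and ribosomal proteins (0 mM replicates 1 and 2, 0.216 and 0.214). Mobile elements had 2 of 96 lower, Nwi_2105 (-2.59 ± 0.34) and a phage gene (Nwi_0862, -1.96 ± 0.36), and the same 2 adjusted over the list alone. Oxidative stress defence had 1 of 19 lower, Nwi_0492 (-2.33 ± 0.33), also adjusted over the list alone, with an upward median of 0.33. NorC (Nwi_2313, -4.38 ± 1.18) and NorB (Nwi_2314, -3.31 ± 0.90) passed the threshold only when adjusted over the nitrite oxidation list alone (2 lower, 0 higher), as did Nwi_1207 (-4.42 ± 1.15) and Nwi_1206 (-3.52 ± 0.98) over the storage polymer list alone (2 lower, 0 higher) and Nwi_0922 (2.73 ± 0.53) over the translation list alone (1 higher, 0 lower). The 9 remaining lists tested, of ammonium assimilation, carbon dioxide fixation, conjugation, denitrification, iron, metal efflux, osmotic stress, outer membrane and terminal oxidases, had 0 members past it either way and no camera call with all 6 libraries. Carbon dioxide fixation and translation did pass camera upward with the replicate number as a block (0.0309 and 0.0262) and without 0 mM replicate 3 (0.000133 and 0.000203). The 3 nitrogen regulation genes also had 0. With edited lists, denitrification had 0 of 7 members past the threshold, and 2 lower and 0 higher adjusted over the list alone. For terminal oxidases the median of 0.22 and the mean of -0.22 differed in sign, and camera gave an upward direction for denitrification and outer membrane genes, whose medians were -0.37 and -0.12.

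None of the genes named beforehand for ammonium assimilation, nitrite oxidation, carbon fixation and signalling passed the threshold at 25 against 0 mM by edgeR on all 6 libraries. Glutamate synthase had values of 0.54 ± 0.45 (Nwi_2953) and 0.77 ± 0.65 (Nwi_2954), glutamine synthetase (Nwi_1904) -0.49 ± 0.36, glutamate dehydrogenase (Nwi_2286) -0.54 ± 0.30, and the PII genes 0.36 ± 0.26 (Nwi_0076), -0.69 ± 0.31 (Nwi_1903) and 0.18 ± 0.92 (Nwi_2931). Nitrite oxidoreductase had -0.52 ± 0.51 (Nwi_0774), 0.85 ± 0.87 (Nwi_2068), 0.45 ± 0.51 (Nwi_0776) and -1.47 ± 0.88 (Nwi_0965). RuBisCO had 0.78 ± 0.68 (Nwi_1987) and -0.10 ± 0.54 (Nwi_2928) for cbbL and -0.61 ± 0.22 (Nwi_1971), 1.47 ± 0.77 (Nwi_1986) and -0.28 ± 0.73 (Nwi_2929) for cbbS. The autoinducer synthase (Nwi_0626) had -0.98 ± 0.33 and its LuxR partner (Nwi_0627) -0.60 ± 0.25. For nirK (Nwi_2648) the value was -1.84 ± 1.71, with the opposite sign by limma-voom (0.36), with the replicate number as a block (0.46) and without 0 mM replicate 3 (3.04, past the threshold). Without 0 mM replicate 3 the threshold was also passed by glutamate synthase Nwi_2953 (1.16) and Nwi_2954 (1.97), glutamate dehydrogenase Nwi_2286 (-0.76), nitrite oxidoreductase Nwi_2068 (2.38) and Nwi_0965 (-1.95), cbbL Nwi_1987 (2.03), cbbS Nwi_1986 (3.01) and Nwi_2929 (1.06, of the opposite sign, as under limma-voom and with the block) and the autoinducer synthase Nwi_0626 (-1.06). DESeq2 on all 6 libraries called Nwi_0626 (-0.96) and Nwi_0627 (-0.59).

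The calls at 25 against 0 mM rested on every library but 0 mM replicate 3: without 0 mM replicate 3 edgeR called 525 higher and 518 lower, with all 70 genes among them. Without any 1 of the others it called 0, with 673, 457 and 403 genes at an unadjusted p under 0.05 without 25 mM replicates 1, 2 and 3 and 457 and 436 without 0 mM replicates 1 and 2. DESeq2 and limma-voom, run on all 6 libraries alone, called 201 higher and 409 lower, and 2 and 66. The fit of all 9 libraries called 85 higher and 275 lower, and the replicate number as a block in the 6 libraries 0 and 0 (559 at an unadjusted p under 0.05). Upper-quartile scaling, under which the median of the genes moved from -0.04 to 0.11, called 5 and 42.

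At 1 against 0 mM ammonium no gene passed the threshold by edgeR, and amino acid biosynthesis was the list with an upward shift and mobile elements the one with a downward shift. Both list calls, by camera with a preset correlation, were lost at adjusted p = 0.936 with an estimated correlation. The first was also lost with edited lists and the preset correlation, at adjusted p = 0.140, and the second was kept with them, at adjusted p = 0.0234. With the replicate number as a block in the 6 libraries, carbon dioxide fixation also passed camera upward (0.0407). Tryptophan synthase alpha (trpA, Nwi_0054), the last step of tryptophan synthesis, was higher in all 3 libraries at 1 mM, with a log2 fold change of 0.98 ± 0.21 (adjusted p = 0.281). The methionine synthesis gene metX (Nwi_0585) had 0.91 ± 0.21 (adjusted p = 0.281). Of 2910 genes tested, edgeR called 0 higher and 0 lower, with 387 at an unadjusted p under 0.05 and a smallest adjusted p of 0.274, limma-voom called 0, and DESeq2 111 higher and 75 lower. In every list 0 members were past the threshold by edgeR, also adjusted over the list alone.

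Amino acid biosynthesis had a median log2 fold change of 0.19 over 55 genes (camera adjusted p = 0.0377) and mobile elements, which are transposases, integrases and phage genes, of -0.27 over 82 genes (adjusted p = 0.0440). Each had adjusted p = 0.936 with an estimated correlation. The first call was lost without 0 mM replicate 1 (0.270) or 2 (0.268) and the second without 1 mM replicate 2 (0.183) or 0 mM replicate 2 (0.542), while without 0 mM replicate 3 camera called 9 lists. ATP synthase (median -0.28) and ribosomal proteins (median -0.48) were given an upward direction by camera, opposite to their medians, at adjusted p = 0.422 and 0.449. Without 0 mM replicate 3 camera called both upward, at adjusted p = 9.8e-06 and 4.6e-12. Medians and camera directions also differed for denitrification (-0.07), outer membrane (-0.10), storage polymers (-0.06), terminal oxidases (-0.15), translation (-0.10) and metal efflux (-0.01), none of them called.

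Genes of nitrogen assimilation had log2 fold changes at 1 against 0 mM of -0.88 ± 0.31 for PII Nwi_1903, 0.33 ± 0.24 for Nwi_0076, 0.98 ± 0.78 for Nwi_2931, -0.11 ± 0.40 for glutamine synthetase Nwi_1904, 0.15 ± 0.43 and 0.34 ± 0.65 for glutamate synthase Nwi_2953 and Nwi_2954, and -0.12 ± 0.26 for glutamate dehydrogenase Nwi_2286. Nitrite oxidoreductase had -0.11 ± 0.50 (Nwi_0774), -0.28 ± 0.83 (Nwi_2068), 0.75 ± 0.63 (Nwi_0776) and -0.61 ± 0.74 (Nwi_0965), and RuBisCO 0.61 ± 0.80 (Nwi_1987), -0.50 ± 0.55 (Nwi_2928), -0.48 ± 0.22 (Nwi_1971), 1.29 ± 1.02 (Nwi_1986) and -0.32 ± 0.71 (Nwi_2929). The value was -3.15 ± 1.78 for nirK (Nwi_2648), -0.17 ± 0.35 for the autoinducer synthase (Nwi_0626) and -0.64 ± 0.23 for its LuxR partner (Nwi_0627). In 1 mM replicate 1, nirB (Nwi_0719) stood at 83.6 CPM and cynS (Nwi_1302) at 189 CPM, against 6.11 and 9.63 CPM and 17.8 and 23.3 CPM in replicates 2 and 3. Without 0 mM replicate 3, edgeR called 402 genes higher and 342 lower at 1 mM, and cbbS Nwi_2929 turned from -0.32 to 0.95 (also above 0 by limma-voom and with the block). Past the threshold without it were that gene, PII Nwi_2931 (2.42), glutamate synthase Nwi_2953 (0.75) and Nwi_2954 (1.53) and the LuxR partner Nwi_0627 (-0.68, -0.63 and past it by DESeq2 on all 6 libraries), while nirK stood at 1.65 and did not pass. The fit of all 9 libraries called 3 higher and 0 lower.

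Of the genes lower at 25 than at 0 mM, 60 of 68 were also lower at 25 than at 1 mM, where independent lists would share 7.12, and 1 of the 2 higher genes was also higher, where they would share 0.147. Both comparisons share the 25 mM libraries. In 10 simulations of unchanged groups that shared them, at most 0 genes were called in both. The simulations leave out the effects and the independent value leaves out the shared libraries, so part of the excess can come from the shared libraries. Across 2907 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.785, against 0.493 in 100 simulations, with a covariance of 0.522 against 0.106 simulated. No gene was called at both 1 and 25 mM against 0 mM by edgeR, which called 0 at 1 mM (387 at an unadjusted p under 0.05). The fold changes at 1 and at 25 mM correlated at r = 0.639 across 2907 genes, against 0.503 in simulations of unchanged groups sharing the 0 mM libraries, with a covariance of 0.342 against 0.110 simulated. These simulations gave a gene the same spread in all libraries, whereas 0 mM replicate 3 stood apart from its group. Without this library, edgeR called 298 genes higher and 260 lower at both 1 and 25 mM, and 0 in opposite directions. Independent lists would share 72.0 and 60.4. Both comparisons still share 0 mM replicates 1 and 2, and the correlation and covariance were not computed without replicate 3. So no shared effect of 1 and 25 mM follows from these values.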

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

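The fit of 6 libraries with the replicate number as a block, the fits without 0 mM replicate 3 in all 9 libraries, the second version of the counts and the edited lists were chosen only after results were seen; the other alternatives were planned. At 1 against 0 mM, DESeq2 called 111 genes higher and 75 lower, the fit of all 9 libraries 3 and 0, and that fit without 0 mM replicate 3 330 and 280, against 0 and 0 by edgeR (387 at an unadjusted p under 0.05), and leaving out 1 library gave 0 to 402 higher and 0 to 342 lower, the highest without 0 mM replicate 3. At 25 against 0 mM (2 and 68), upper-quartile factors gave 5 and 42, DESeq2 201 and 409, all 9 libraries 85 and 275, the replicate block in all 9 libraries 35 and 132, the replicate block in the 6 libraries 0 and 0 (559 at an unadjusted p under 0.05), stable RNA left out 2 and 44, and all 9 libraries without 0 mM replicate 3 602 and 575. Leaving out 1 library gave 0 to 525 higher and 0 to 518 lower: the highest without 0 mM replicate 3, and 0 without any of the others. At 25 against 1 mM (215 and 307), all 9 libraries gave 35 and 117, the replicate block in all 9 libraries 2 and 3, the replicate block in the 6 libraries 180 and 286, a 2-fold threshold 109 and 211, and leaving out 1 library 54 to 383 and 135 to 449, lowest without 25 mM replicate 3 and highest without 25 mM replicate 1. At 25 against 1 mM, all 9 libraries without 0 mM replicate 3 gave 245 and 364. That library is in neither group compared there, so the drop to 35 and 117 in the fit of all 9 went with it. The fewer calls at 2-fold follow from its construction. For the rest the cause was not tested.

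Camera moved 2, 8 and 6 lists at 1 against 0, 25 against 0 and 25 against 1 mM. With the replicate number as a block in the 6 libraries it moved 3, 10 and 5, with an estimated correlation 0, 0 and 0, and with edited lists and an estimated correlation 0, 0 and 0. For nitrogen sources at 25 against 0 mM the estimated correlation was -0.067, below the preset 0.01, yet the unadjusted p of camera rose from 0.0139 to 0.0590. For quorum sensing at 25 against 1 mM the estimated correlation was 0.0186, near the preset, and the unadjusted p of camera rose from 0.0107 to 0.0714. So the loss of these calls does not measure correlation between genes alone. Fry moved 0, 2 and 9 lists in that order. At 25 against 0 mM these were nitrogen sources (adjusted p = 0.00214) and flagella and chemotaxis (adjusted p = 0.0126). At 25 against 1 mM it also moved oxidative stress defence, storage polymers and nitrogen sources (each at adjusted p = 0.0246). Camera with edited lists moved 1, 8 and 8, the 8 counting the Flp pilus list and at 25 against 1 mM also iron uptake (adjusted p = 0.0400). Leaving out 1 library moved 0 to 9 lists at 1 against 0 mM (0 without 0 mM replicate 2, 9 without 0 mM replicate 3), 5 to 9 at 25 against 0 mM (5 without 25 mM replicate 1, 0 mM replicate 1 or 0 mM replicate 2) and 5 to 7 at 25 against 1 mM. Genes called at both 1 and 25 mM against 0 mM numbered 0 by edgeR, 93 by DESeq2, 2 in the fit of all 9 libraries and 514 in that fit without 0 mM replicate 3, and leaving out 1 library gave 0 to 558. The cause was not tested.

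Of the named genes, cbbS Nwi_2929 turned in sign without 0 mM replicate 3 in all 9 libraries, at 1 against 0 mM from -0.32 to 0.95 (-0.76 to 0.95 over the libraries left out) and at 25 against 0 mM from -0.28 to 1.02 (-0.74 to 1.06). For nirK Nwi_2648 the value at 25 against 0 mM turned from -1.84 to 3.02 (-2.41 to 3.04). These turned values of Nwi_2929 and nirK passed the threshold in that fit. In the same fit other signs turned without passing it. At 1 against 0 mM these were nirK, glutamine synthetase Nwi_1904, nitrite oxidoreductase Nwi_2068 and cbbL Nwi_2928, and at 25 against 0 mM Nwi_2928. Further signs of values not past the threshold turned under other alternatives. No named gene past the threshold by edgeR turned in sign under any alternative run. Of 800 values of genes named by rule under alternatives other than left-out libraries at 25 against 1 mM, 720 kept their side of the threshold, 78 lost the call and 2 gained it. Of the 78, 46 were lost with the replicate block in all 9 libraries and 29 in the fit of all 9 libraries. For 25 against 0 mM the kept, lost and gained values were 368, 24 and 11 of 405, and at 1 against 0 mM 200, 0 and 7 of 208. The remaining 2 and 1 values turned in sign and passed the threshold. Values not past it under either setting count as kept even where their sign turned. The authors' draw made totals about equal within a table, but counts outside stable RNA ran from 1174901 to 2327465 per library at 1 against 0 mM, 1512751 to 2508726 at 25 against 0 mM and 1603562 to 3427199 at 25 against 1 mM. In simulated data 4.20% of 2-fold changes at 25 against 0 mM were recovered, against 51.5% at 25 against 1 mM.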

Other observations

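Chosen only after results were seen were the Flp pilus list, the genes beside Nwi_0962, the tests of a swap, of a 0 mM library under the 1 mM label, of mixed-in RNA and of the stable RNA share, the tests of the 25 mM label over higher and over lower genes alone, and the counts over other splits of the libraries. The tests of the 25 mM label over all called genes, of the 1 mM label and of abundant coding genes were set beforehand.

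Genes of a Flp pilus, an adhesive surface fibre, lay next to each other in locus order and were lower at 25 mM. At 25 against 1 mM, 9 of 11 were lower and 0 higher (11 and 0 adjusted over the list alone), with a median log2 fold change of -1.68 and CpaB (Nwi_0302), part of the assembly machinery, at -2.04 ± 0.21. Against 0 mM, 5 of 11 were lower and 0 higher (11 and 0 adjusted over the list alone), with a median of -2.06. The pilin gene itself (Nwi_0304) had -1.19 ± 0.38 (adjusted p = 0.0656) at 25 against 1 mM and -2.11 ± 0.41 (adjusted p = 0.0527) at 25 against 0 mM, by edgeR not past the threshold in either. Camera gave adjusted p = 2.5e-08 and 1.3e-08 in these comparisons, and adjusted p = 0.292 and 0.50 with an estimated correlation. The list was picked from these values, so its test is not independent evidence.

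Genes beside the type I secretion ATPase PrtD (Nwi_0962) were lower with it. The membrane fusion protein HlyD (Nwi_0963), the periplasmic part of such exporters, had -2.56 ± 0.26 at 25 against 1 mM and -2.62 ± 0.33 at 25 against 0 mM. Nwi_0961, without a product name, had -1.65 ± 0.26 and -2.51 ± 0.30, and Nwi_0964, a repeat protein, -1.83 ± 0.42 and -2.52 ± 0.47. All 3 passed the threshold by edgeR in both comparisons. Each lost its call at 25 against 0 mM without any 1 library other than 0 mM replicate 3, at adjusted p up to 0.264, and at 25 against 1 mM Nwi_0964 lost it without 25 mM replicate 2, 25 mM replicate 3 or 1 mM replicate 1, at adjusted p up to 0.0856.

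0 mM replicate 3 stood apart from the other libraries at 0 mM. A swap with a library at 1 or 25 mM is argued against, since each of those correlated better with its own group than with 0 mM replicates 1 and 2, by at least 0.0444. A 1 mM library under this label is argued against too: on a scale from the 1 mM mean at 0 to the 25 mM mean at 1, over 519 genes called between them, it lay at 0.620, against 0.0167 to 0.168 for 1 mM libraries (SD 0.0822). A 25 mM library under this label stays open over those genes together, since 0.620 was within 1 SD (0.212) of the 25 mM range of 0.647 to 1.06, and over the higher genes at 0.813 (0.489 to 1.09), but over the lower genes it lay at 0.521, below 0.754 to 1.05 by more than their SD of 0.153, and nirK stood at 551 CPM against at most 77.1 CPM at 25 mM. A difference in how this culture grew may also be open; no biological explanation was tested.

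Most coding genes, 77.8%, lay above 0 in the authors' fold changes at 25 against 0 mM, with a median of 0.58, while the median was -0.04 after TMM scaling. The share of stable RNA is argued against as the whole cause, since the log2 ratio of the remaining totals was 0.225 and left a median of 0.355. At 25 against 1 mM, where 78.0% lay above 0 with a median of 0.49, the same step left 0.09, so there this share stays open. At 25 against 0 mM, with the 100 most abundant other genes, which took 42.0% of the remaining counts at 0 mM and 33.6% at 25 mM, left out as well, the median was 0.160. This value lies between the bounds set for and against that explanation, so abundant genes and a wider change of coding RNA with ammonium cannot be told apart. No biological explanation was tested.

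1 mM replicate 1 carried nirB (Nwi_0719), nirC (Nwi_0720) and cynS (Nwi_1302), genes of nitrite and cyanate use, at 83.6, 47.7 and 189 CPM, against 6.11 and 9.63, 2.97 and 4.18, and 17.8 and 23.3 CPM in replicates 2 and 3. A 0 mM library under its label is argued against, since its lowest correlation with its own group exceeded its highest with a 0 mM library by 0.0444. RNA of a 0 mM culture mixed in is argued against for nirC (Nwi_0720), and so as the whole cause, since its level lay above the 8.75 to 21.0 CPM of the 0 mM libraries by more than their SD of 6.21, a needed share of 2.52. For nirB (Nwi_0719), above 21.6 to 63.8 CPM by less than their SD of 21.3 (needed share 1.35), and for cynS (Nwi_1302), within 140 to 380 CPM, it stays open. The 67 genes lower at 25 than at 0 mM, the set planned for this test, were higher at 0 mM than in 1 mM replicates 2 and 3 by a median log2 ratio of only 0.39 and so could not show it. Only 3 other genes were at least 2-fold higher in every 0 mM library than in those replicates, and they implied a median share of 0 mM RNA of 0.237 where cynS needs at least 0.469, too few genes to decide for cynS. A lower ammonium level in that culture could stay open too, as the labels give no measured residual ammonium; no biological explanation was tested.

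Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. The real split called 522 genes at 25 against 1 mM and the highest other 0, so 1 of 10 splits gave as many. Of the other splits, 3 part every pair of equal replicate number as the real one does, and they called 0. At 25 against 0 mM the real split called 70 and the highest other 12 (1 of 10), with 678 and 716 genes at an unadjusted p under 0.05. At 1 against 0 mM the real split called 0 and the highest other 20 (10 of 10), the 20 with 1 mM replicate 1 grouped with 0 mM replicates 1 and 2, which points to a structure of the samples. Both other splits that part 0 mM replicate 3 from 0 mM replicates 1 and 2 called 0. They had 332 and 422 genes at an unadjusted p under 0.05, against 458 in the split with 20 calls. The real split had 387 and the remaining splits 4 to 57. By unadjusted p the structure among the other splits therefore follows 0 mM replicate 3, while the 20 calls arose in only 1 of them. For lists moved, the real and highest other values were 6 and 7 (3 of 10), 8 and 9 (3 of 10), and 2 and 9 (10 of 10) in that order.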
